A study of Caenorhabditis elegans with 4 samples.

How the data were processed

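Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans adults of the fem-2(b245) strain, a mutant of the sex determination gene fem-2, listed as germline-containing young adult hermaphrodites at 20 °C. The labels' growth protocol speaks of gravid adults. The target was MRE-11, the nuclease of the complex that processes DNA double-strand breaks, and the antibody was an affinity-purified rabbit polyclonal. Per the labels' protocols, ground frozen worms were crosslinked in EGS for 20 min and then in EGS with formaldehyde for 10 min, and chromatin was sonicated. The series holds 2 MRE-11 ChIP libraries and 2 input libraries. Samples were grouped by their titles. The labels do not say whether the replicates came from separate worm cultures. The p-values describe these lists, over peaks, positions or chromosomes, and none measures spread between libraries or cultures. The labels assign no library to a sequencing batch.

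The deposited data used here were 3 peak lists. Each ChIP replicate has its own list, and 1 list covers the whole series. No processed values of the input libraries were used here, and the input that served as control for each list is not given in the sources used here. Per the file headers, coordinates are on WormBase WS220, and the submitters' processing notes name the build ce10 and the aligner BWA with no version. Per the file contents, the authors called the replicate lists with MACS and the series-wide list with MACS v2. Whether reads of the replicates were pooled for the series-wide list is not given in the sources used here. The authors' files give a position and a score for each peak. The scale of the deposited score is not named in the files. Scores in the replicate lists started just above 50 and piled up at 3100, and scores in the series-wide list started at 1.30. Scores of the replicate lists and of the series-wide list are therefore on different scales and were never compared with each other. A score is the peak's own value as the authors' caller gave it, and it was used to rank or describe peaks within a list and, between the replicate lists only, to correlate matched peaks and to rank regions found in both. Differences of scores between peak groups describe the lists and are not fold changes of binding. Read depth is unknown, so no value here carries an interval from read counts.

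All statistics were computed from the lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A peak counted as matched if at least 1 bp overlapped a peak of the other list. The matched share was set against 10000 circular shifts of one list within each chromosome, one-sided. The files give no chromosome lengths, so the largest peak end over the 3 lists stood for the length of each chromosome. The share of peaks on X was tested against the X share of length with a two-sided exact binomial test, which takes peaks as independent. Each chromosome was divided into 3 equal parts, and the density of peak midpoints in the central part was compared with that in the outer parts (the arms) by an exact two-sided sign-flip permutation test over 6 chromosomes. Differences in median score or width used two-sided permutation tests with 100000 resamples. Scores of matched peaks were compared by Pearson's r on log10 scores and Spearman's rho over peaks, each replicate 2 peak taking its strongest overlapping replicate 1 peak. The share of peaks with a neighbour within 5 kb was set against 1000 random placements within chromosomes, one-sided. Random placements could overlap each other, and overlapping ones counted as neighbours. Where listed peaks do not overlap, this raises the random share and makes the test stricter. Placement was uniform along each chromosome, so uneven density, as between centre and arms, works the other way. A share above random therefore does not separate grouping from uneven density. Shares carry 95% exact Clopper-Pearson intervals, which also take peaks as independent, as do the Fisher's exact tests. The 18 planned p-values were adjusted together by the Benjamini-Hochberg method. A further 13 tests were chosen after the lists had been seen and were adjusted together separately. This division was itself settled after the values were seen, after adjusting 23 and then all 31 tests together. The later tests cover the X share of the strongest 5% of peaks, matching of X peaks, position of X peaks, and width. One of the 13, on the presence of strong replicate 1 peaks in the series-wide list, is not reported, because that list is not independent of the replicates.

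Regions named in the report were fixed by rule before the data were examined, and others named in the closing observations were chosen after their values were seen. Those under the rule are the 10 strongest peaks of the series-wide list, the 10 strongest present in both replicates by mean rank, and the 5 strongest of each replicate with no match. The 3 densest windows of 100 kb per list and the 3 widest series-wide peaks complete the rule. Other settings fixed in advance covered the overlap rule, a stricter score threshold, list length, the placement model, covered bases, merging of close peaks, the division of chromosomes, width in place of score and the neighbour distance. Settings of the overlap rule were set against 100 circular shifts, and the others against 1000. The code was tested on simulated lists. A shared share of 60% was recovered as 60.0% on average, after correction for random overlap, over 20 simulated pairs sized like the replicate lists. Of 20 unrelated pairs, 1 was called. The matched shares reported below are not corrected in this way and stand beside their random share. An X to autosome ratio of 0.4 came back as 0.395 over 20 lists sized like replicate 1, and 1 of 20 lists without depletion was called. The planned assignment of peaks to genes, and the 18 gene lists that went with it, were not run. The gene table at hand is on the WBcel235 assembly, and coordinates were not mixed between builds.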

Results

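MRE-11 occupancy was profiled by ChIP-seq in fem-2(b245) adult worms, with 2 ChIP libraries and 2 input libraries. The replicate 1 list held 2471 peaks with a median width of 1780 bp, which covered 5.36% of the chromosomes. The replicate 2 list held 1294 peaks with a median width of 2272.5 bp, which covered 3.36%. The series-wide list held 2720 narrower peaks with a median width of 300.0 bp, which covered 1.096%. All peaks lay on the 5 autosomes and on X. Sequencing depth was not given, so a region without a peak is one where no peak was listed, not one shown to lack MRE-11.

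The first comparison asked how far the replicates mark the same regions. Nearly all replicate 2 peaks recurred in replicate 1, whereas many replicate 1 peaks had no counterpart. Of the replicate 2 peaks, 1267 of 1294 (97.9%, 95% interval 96.98 to 98.6%) overlapped a replicate 1 peak, against 13.3% on average after circular shifts. Of the replicate 1 peaks, 1278 of 2471 (51.7%, 49.7 to 53.7%) overlapped a replicate 2 peak, against 7.17% after shifts. Both shares exceeded every one of the 10000 shifts (permutation p = 1e-04, the smallest they can give, adjusted p = 2e-04). When the replicate 1 list was limited to its 1294 strongest peaks, 79.1% of replicate 2 peaks and 78.7% of those replicate 1 peaks were matched.

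Among matched peaks, those with higher scores in one replicate tended to have higher scores in the other. Across the 1267 matched replicate 2 peaks, scores correlated with Pearson's r = 0.79 on the log10 scale and Spearman's rho = 0.81 (permutation p = 1e-05 for each, the smallest possible, adjusted p = 2.57e-05). On the autosomes alone rho was 0.81 over 1218 pairs, and on X it was 0.89 over 49. These are correlations across peaks, which are not independent replicates. A score of 3100 or more, where the lists pile up, was reached by 21 replicate 1 peaks and 23 replicate 2 peaks. In 12 regions it was reached in both replicates, and 10 of these were on X. The other 2 were chromosome III 7178204 to 7183017 and chromosome V 125738 to 129469. The X regions first in order were 2995929 to 2998083, 4207927 to 4210624, 6295428 to 6297577 and 8034929 to 8037577. They were followed by 9464562 to 9467174, 11092883 to 11096140, 11936289 to 11938345 and 12362020 to 12364174. All 12 regions tied in mean rank, so the tie was broken by chromosome order, which left 2 X regions out of the 10 taken by mean rank.

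**Figure D1:**
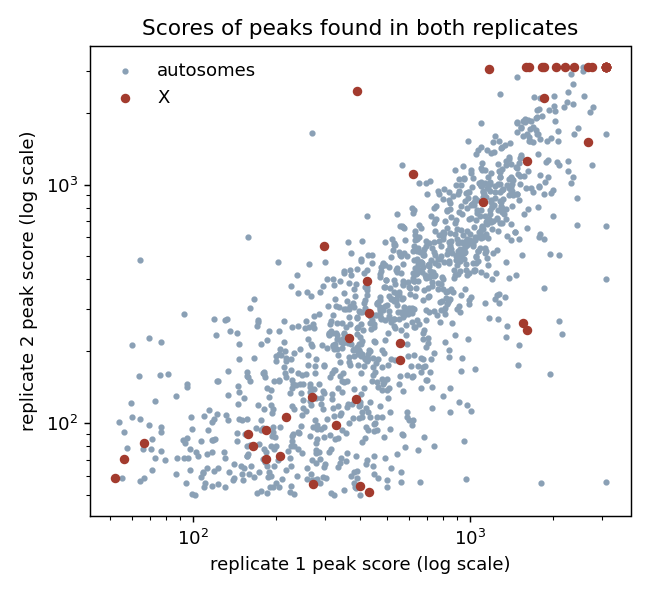
Scores of the 1267 matched peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), both in the peak caller's units. Each point is a replicate 2 peak with its strongest replicate 1 partner, X in red and autosomes in grey-blue. The points rise together (Spearman's rho = 0.81), and X points gather at the score of 3100 at the upper right.

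Peaks found in 1 replicate only had lower median scores. Matched replicate 1 peaks had a median score of 547, against 128 for the 1193 unmatched ones, a difference of 418 (permutation p = 1e-05, adjusted p = 2.57e-05). Matched replicate 2 peaks had a median score of 309, against 82.5 for the 27 unmatched ones (permutation p = 0.0178, adjusted p = 0.0247). The matched share of replicate 1 peaks was 9.68% in the weakest decile by score, 46.6% in decile 5 and 93.1% in decile 9. It was lower, at 84.2% (79.1 to 88.5%), in the strongest decile. The strongest unmatched replicate 1 peaks were chromosome I 13609913 to 13616035, chromosome I 15059825 to 15071786, chromosome V 9338197 to 9344857, X 108712 to 114711 and X 289358 to 295743. Their scores were 3100 or above. The peak ending at 15071786 is the last on the right end of chromosome I, the chromosome end that carries the ribosomal DNA array in this species. The strongest unmatched replicate 2 peaks scored less, led by chromosome II 6296212 to 6297568 with 764 and chromosome II 551671 to 553148 with 273. The next were chromosome III 5541560 to 5543501 (score 138), chromosome II 11990847 to 11992126 (score 125) and chromosome III 11930977 to 11932470 (score 122.4).

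**Figure D2:**
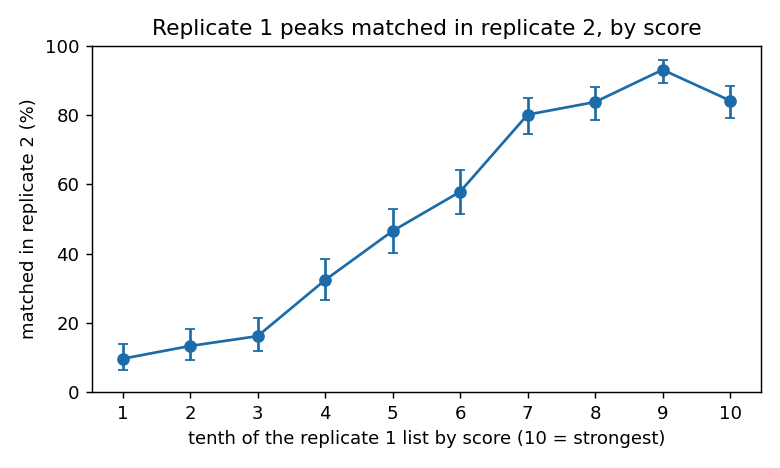
Share of replicate 1 peaks that overlap a replicate 2 peak (y axis, percent) for each decile of the replicate 1 score (x axis, 10 the strongest). Bars are 95% Clopper-Pearson intervals, and the share climbs from 9.68% to 93.1% in decile 9 before 84.2% in decile 10.

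The series-wide list was then set against the replicates. Of its 2720 peaks, 1618 (59.5%, 57.6 to 61.3%) overlapped peaks of both replicates and 933 (34.3%, 32.5 to 36.1%) overlapped replicate 1 only. A further 7 overlapped replicate 2 only, and 162 (5.96%, 5.10 to 6.91%) overlapped neither. Peaks overlapped by both had a median score of 11.35, against 5.86 for those with replicate 1 only and 4.49 for those with neither. In the other direction, 93.9% of replicate 2 peaks and 78.8% of replicate 1 peaks held a series-wide peak. Because the series-wide list is not independent of the replicates, no test was made. The widest series-wide peaks were chromosome III 324518 to 328061 (3544 bp), X 16930206 to 16933595 (3390 bp) and chromosome III 321839 to 324451 (2613 bp), each present in both replicates.

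The next comparison asked how peaks were spread over the chromosomes. X is largely silent in germline nuclei of this species, which is why X was set against the autosomes. The chromatin came from ground worms, in which germline and somatic nuclei were not separated, and a role of silencing was not tested. X held the fewest peaks per Mb in each of the 3 lists, and chromosome III held the most. In replicate 1, X had 9.54 peaks per Mb, against 28.8 ± 6.98 (SD, n = 5) over the autosomes. In replicate 2, X had 2.88 peaks per Mb, against 15.7 ± 4.63 (SD, n = 5). On the series-wide list, X had 10.6 peaks per Mb, against 31.8 ± 8.60 (SD, n = 5). Chromosome III reached 37.1, 21.1 and 42.6 peaks per Mb in these lists. Chromosome V was the lowest autosome, with 19.04, 8.73 and 19.3.

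Pooled over the length of the autosomes, the density was 27.9 (replicate 1), 15.1 (replicate 2) and 30.7 (series-wide) peaks per Mb. The density on X relative to the pooled autosomes was 0.341 (95% interval 0.290 to 0.399) in replicate 1, 0.191 (0.141 to 0.252) in replicate 2 and 0.345 (0.296 to 0.401) in the series-wide list. The mean of the replicates was 0.27 ± 0.11 (SD, n = 2). The exact binomial p was 6.82e-56 in replicate 1, 8.87e-52 in replicate 2 and 1.71e-60 in the series-wide list. The adjusted values were 6.13e-55, 5.32e-51 and 3.08e-59. These tests take peaks as independent. A ranking of 6 chromosomes cannot give an exact p below 0.167.

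**Figure D3:**
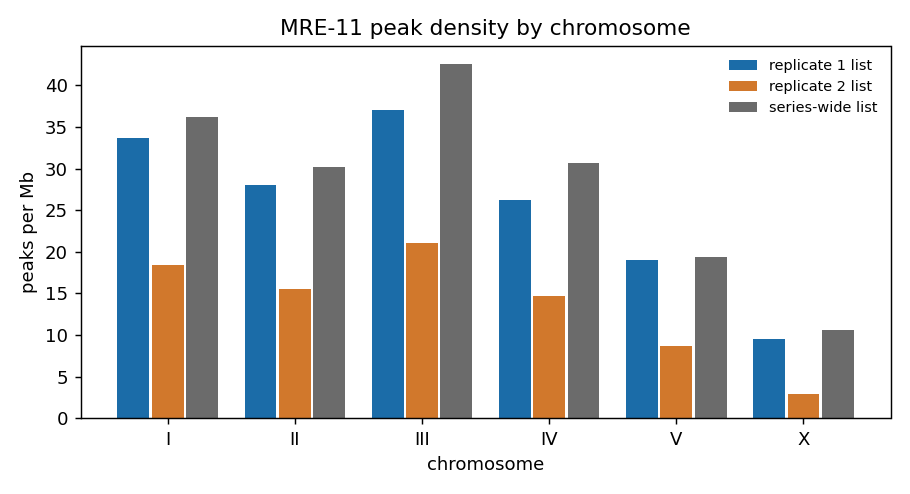
Peaks per Mb (y axis) on each chromosome (x axis) in the replicate 1, replicate 2 and series-wide lists, 1 bar per list with no replicate error. X is the lowest in each list, at 9.54, 2.88 and 10.6 peaks per Mb.

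The X peaks, though few, were frequent among the highest scores. All 10 strongest peaks of the series-wide list were on X, and each overlapped a peak in both replicates. Those at the highest score, 54.34, were at 1626598 to 1627665, 2996305 to 2997609, 8035764 to 8037206, 14525139 to 14526749 and 16055853 to 16056998. The next were 806426 to 806922 (score 53.49), 7181460 to 7182128 (score 53), 11093332 to 11094652 (score 52.42), 4208350 to 4209848 (score 51.47) and 1344515 to 1345435 (score 50.95). In replicate 2 these regions scored between 2295 and 3100, and in replicate 1 between 1170.0 and 3100. At the score of 3100 and above, X supplied 12 of 21 peaks in replicate 1 and 19 of 23 in replicate 2. The highest replicate 1 score, 3108.49, was on chromosome I, and in replicate 2 peaks on chromosomes II, III and V shared the score of 3100 with X. In the series-wide list the highest autosomal score was 50.58, on chromosome III, just below the 50.95 that closes the 10 strongest.

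In a test chosen after these values were seen, X supplied 20.97% of the strongest 5% of replicate 1 peaks, against 6.84% of the whole list. The corresponding shares were 33.8% against 3.94% in replicate 2 and 17.6% against 6.91% in the series-wide list. Fisher's exact test gave p = 9.56e-08, 3.36e-17 and 1.09e-05 (adjusted p = 3.11e-07, 4.36e-16 and 1.77e-05). Among the strongest 1%, X supplied 52%, 82.6% and 50% (Fisher's exact p = 1.16e-09, 4.04e-25 and 1.41e-10, unadjusted). In replicate 2 this set held all 23 peaks tied at 3100, more than 1% of the list. Its share therefore restates the 19 of 23 given above. Among the strongest 10% it supplied 11.7%, 18.5% and 9.56%, and the series-wide share did not pass (Fisher's exact p = 0.0772).

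The median score of X peaks did not follow one direction, whereas their median width was lower in each list. In replicate 2 the median score was 847 on X, against 301 on the autosomes (permutation p = 1e-05, adjusted p = 2.57e-05), while the median width was 1669 bp, against 2313 bp (permutation p = 0.0030, unadjusted). In replicate 1 it was 164 on X, against 281 (permutation p = 0.00193, adjusted p = 0.0030), and the median width was 1309 bp, against 1803.5 bp (permutation p = 1e-05, unadjusted). For the series-wide list the score was 6.305, against 7.79 (permutation p = 0.0426), and the width was 247.5 bp, against 305 bp (permutation p = 0.0038, unadjusted). The permutation test of the series-wide score did not pass after adjustment over the 18 planned tests (adjusted p = 0.0547), but did when the 13 later tests were included (adjusted p = 0.0489). Among replicate 1 peaks matched in replicate 2, the X median was 1143, against 544 (permutation p = 1e-05, an alternative chosen after seeing the data). Among the unmatched ones it was 114, against 130 (permutation p = 0.198).

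X peaks of replicate 1 were matched less often than autosomal ones. Of 169 X peaks, 48 (28.4%, 21.7 to 35.8%) were matched in replicate 2, compared with 1230 of 2302 autosomal peaks (53.4%, 51.4 to 55.5%). Fisher's exact test, chosen after seeing the data, gave p = 2.58e-10 (adjusted p = 1.12e-09). At the same scores, 71.1 X matches would be expected from the score deciles (permutation p = 1e-04, the smallest it can give).

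**Figure D4:**
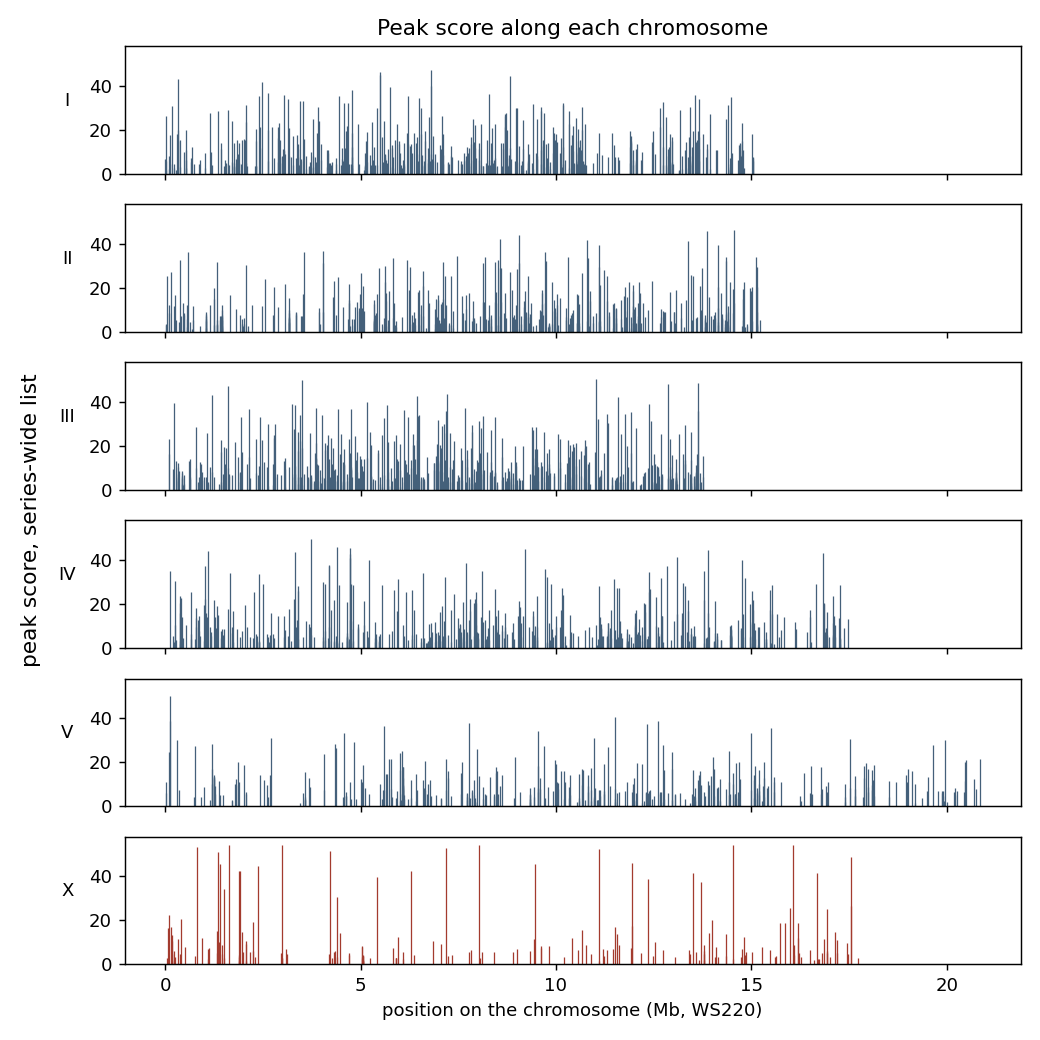
Score of each series-wide peak (y axis, caller's units, same range for every chromosome) by position in Mb on WS220 (x axis), 1 panel per chromosome, X in red. X carries sparse tall peaks up to 54.34 among low ones, and the autosomes carry a denser mixture of heights.

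Position along the chromosomes was compared next, since the arms and centres of worm chromosomes differ in recombination. The 5 autosomes had more peaks per Mb in the central part than in the arms in each list, and X had fewer. In replicate 2 the log2 ratio of centre to arm density ran from 0.60 on chromosome III to 0.97 on chromosome V, and was -1.22 on X. In replicate 1 the autosomes ran from 0.29 on chromosome II to 0.47 on chromosome I, and X was at -0.74. In the series-wide list the autosomes ran from 0.23 on chromosome IV to 0.46 on chromosome V, and X was at -0.80.

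Over all 6 chromosomes the mean log2 ratio was 0.20 ± 0.46 (SD over chromosomes) in replicate 1, 0.43 ± 0.82 in replicate 2 and 0.15 ± 0.48 in the series-wide list. None passed the exact sign-flip permutation test (p = 0.312, 0.219 and 0.469). The adjusted values were 0.352, 0.262 and 0.469, and the smallest p this test can give is 0.0312. For the autosomes alone the p was 0.0625 in each list, the smallest that 5 chromosomes allow. The contrast of X with the autosomes, tested after it was seen, was larger than counting error if peaks are taken as independent. These tests pool the autosomes and do not measure spread between chromosomes. In replicate 1, 23.1% of X peaks lay in the central part, against 39.6% of autosomal peaks (Fisher's exact p = 1.26e-05, adjusted p = 1.82e-05). In replicate 2 the shares were 17.6% (9 of 51) and 45.7% (Fisher's exact p = 7.08e-05, adjusted p = 7.67e-05). Series-wide peaks gave 22.3% and 38.6% (Fisher's exact p = 5.14e-06, adjusted p = 1.34e-05).

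Finally, grouping of peaks was examined. In the series-wide list, 50.7% of peaks had a neighbour within 5 kb, against 28.3% after random placement (permutation p = 0.001, the smallest possible, adjusted p = 0.0018). Some of these neighbours lay inside the same replicate 1 peak, and counting such peaks as 1, a choice made after seeing the data, left 2117 peaks. Of these, 20.9% had a neighbour within 5 kb, against 22.6% at random (permutation p = 0.922), but the count removes close neighbours from the list and not from the random placements. In replicate 1 the share was 36.3%, against 32.7% at random (permutation p = 0.0020, adjusted p = 0.0030). It did not pass within 2 kb (21.4% against 20.7%, permutation p = 0.238) or for peaks at or above the median score (18.2% against 20.0%, permutation p = 0.91). In replicate 2 it was 21.3%, against 21.1% (permutation p = 0.44, adjusted p = 0.465). Because overlapping random placements raise the random share, the tests that did not pass do not show an absence of grouping. Because placement was uniform, those that passed do not separate grouping from uneven density along the chromosomes. The densest 100 kb window of the series-wide list and of replicate 1 was chromosome V 6000001 to 6100000, with 25 series-wide peaks, 14 in replicate 1 and 4 in replicate 2, where it was not among the 3 densest. The mean series-wide window held 2.71. Chromosome III 7100001 to 7200000 was among the 3 densest in both replicates, with 10 and 7 peaks. Chromosome IV 4700001 to 4800000 had the same counts, 10 and 7. It was among the 3 densest of replicate 1, and in replicate 2 it tied at 7 without being among the 3 taken. Other dense windows were chromosome II 11900001 to 12000000 with 8 replicate 2 peaks, the densest of that list, and chromosome I 5600001 to 5700000 with 7. Those of the series-wide list were chromosome IV 15000001 to 15100000 with 17 peaks and chromosome III 13000001 to 13100000 with 16.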

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

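No paired analysis was possible because the values used here come from the ChIP libraries only and values of the input libraries were not used here. Of 78 alternative values, 68 kept their direction and their side of the threshold, or moved by less than the spread. For some of the 68 this was fixed in advance. Leaving out 1 of 2 replicates always moves their mean by less than their SD. The sign-flip test over the autosomes alone cannot give a p below 0.0625, so it could not cross the threshold of 0.05. The alternatives within quintiles of width and score deciles, without X, without left-end peaks, restricted to matched peaks, with the strongest 1% and 10%, with peaks sharing a replicate 1 peak counted as 1, with the middle 50% for X, with chromosomes 1% longer, and with other sets of tests adjusted together were chosen after seeing the data. The share of series-wide peaks matched in both replicates moved from 59.5% to 0.662% under 50% reciprocal overlap, since series-wide peaks are far narrower than replicate peaks, and to 76.3% for peaks at or above the median score. The share of replicate 1 peaks with a neighbour no longer passed the test against random placement within 2 kb (21.4%) or at or above the median score (18.2%). That of replicate 2 passed it within 20 kb (54.4%). Random placements could overlap and then counted as neighbours, so a share that did not pass does not show an absence of grouping. They were uniform, so a share that passed may reflect uneven density along the chromosomes. Counting 1 series-wide peak per replicate 1 peak gave 20.9%, but this removes close neighbours from the list and not from the random placements, so it says nothing about grouping. The X minus autosome difference in replicate 2 turned from a higher score to a width of -644 bp. In replicate 1 it turned from -117 to 599 in score among matched peaks. The X share of the strongest 10% of series-wide peaks, 9.56%, no longer passed. The cause was not tested for the last 3. The adjusted p of the series-wide X score difference was 0.0547 over the 18 planned tests, 0.0515 over 23 and 0.0489 over all 31, by construction, so whether it passes depends on that choice. X to autosome density was 0.19 without replicate 1 and 0.34 without replicate 2, and the mean log2 centre to arm ratio was 0.43 and 0.20. The planned windows around transcript starts and the gene lists were not run. With depth unknown, weak peaks missing from replicate 2 cannot be separated from regions without MRE-11.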

Other observations

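The tests in this part were chosen after the result was seen, except the 90% bound on the matched share of the strongest decile. The 39 unmatched peaks in the strongest decile of replicate 1 were spread over all chromosomes, with 5 on I, 7 on II, 8 on III, 5 on IV, 8 on V and 6 on X. They were wider than the 208 matched peaks of that decile, with median widths of 5551 and 3432.5 bp (permutation p = 1e-05, adjusted p = 1.77e-05). Of the unmatched ones, 51.3% (34.8 to 67.6%) held a series-wide peak, against 99.5% of the matched ones, and a test of this difference is not reported because that list is not independent of the replicates. The widest peaks of replicate 1, chosen after their values were seen, were chromosome III 13583902 to 13599268, chromosome V 17119489 to 17132617 and chromosome I 15059825 to 15071786. None of these 3 was matched in replicate 2, and the latter 2 were also without a series-wide peak.

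At the left chromosome ends, replicate 1 listed 5 peaks that start within 5 kb of base 1, on 4 chromosomes. They were chromosome I 1 to 1495 (score 685), chromosome I 3387 to 4441 (score 56.8), chromosome II 2 to 1213 (score 245), chromosome V 1 to 795 (score 349) and X 1 to 753 (score 203). Replicate 2 listed none there, and the series-wide list had 1, inside the second of these. A probability that none of the 5 would be matched was computed and is not given, because these peaks had been picked for lacking a match.

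Replicate 1 listed far more peaks than replicate 2, and lower sensitivity of the replicate 2 list, from depth or enrichment, is a candidate explanation. As first set, it needed over 90% of the strongest decile of replicate 1 to be matched. The share was 84.2%, with an upper bound of 88.5%, so this prediction was not met. It was also below that of decile 9 (93.1%, 89.2 to 95.9%). At the same scores, X peaks of replicate 1 were matched less often (48 against 71.1 expected). These values argue against a loss of sensitivity that follows the score alone. However, replicate 1 scores rose with peak width (Spearman's rho = 0.75 across peaks), and the 39 strong unmatched peaks were wider than the matched ones. A high score may therefore not mark a region that is easy to detect, so a loss that does not follow the score stays open for the 39 peaks. The remaining deciles were separated only after the 84.2% was seen. Their matched share climbed from 9.68% to 93.1%, as lower sensitivity would give. The interval in decile 9 (89.2 to 95.9%) spans the 90% bound and so decides nothing. Reads from repeated sequence stay open for the 39 peaks, because no sequence was used here. No biological explanation was tested, since the replicates form 1 group.

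X held few peaks but many of the strongest, and the score scale of one peak caller could place this in a single list. The X share of the strongest 5% was at least 17.6% in all 3 lists, with lower bounds of 14.2%, 22.6% and 11.6%. These lie above the X shares of the lists (6.84%, 3.94% and 6.91%). The excess thus appeared in the lists labelled MACS and in the one labelled MACS v2, which is not independent of them. The X share of the list was taken as the bound after the values had been seen. The comparison therefore describes the lists and does not decide on the score scale. For the strongest 10% of series-wide peaks the lower bound, 6.34%, was not above. A first bound at the X share of length, 17.7%, was passed by replicate 2 only for the strongest 5% and by all 3 lists for the strongest 1% (lower bounds 31.3%, 61.2% and 31.3%). The replicate 2 set at 1% was all 23 peaks tied at 3100, more than 1% of that list. A property of the score common to all 3 lists was not tested and stays open.

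Wider X peaks could also raise their scores, and this was tested in 3 ways. The first ranked peaks within quintiles of width and set the X share against the X share of length (17.7%): X supplied 25.6%, 38.5% and 18.1% in replicate 1, replicate 2 and the series-wide list, with lower bounds of 18.2%, 26.7% and 12.1%, so the series-wide list decided nothing. The second compared widths among the strongest 5%, where X peaks were narrower in the replicates (ratios of medians 0.589 and 0.561; permutation p = 1e-05 and 2e-05), which argues against width there, and wider in the series-wide list (1.48; permutation p = 7e-05). The third set the quintile ranking against the X share of the list instead, and all 3 lower bounds passed it. It was chosen after the other results and quintiles are coarse, so in the series-wide list width stays open.

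Antibody cross-reaction and general openness of chromatin at the strong X peaks were not tested, and no biological explanation was tested. Whether these peaks lie at recruitment sites of the dosage compensation complex, which binds X in somatic cells of hermaphrodites, was not analysed here.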
